A study of Homo sapiens with 11 samples.

How the data were processed

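The series holds 11 one-colour Affymetrix arrays hybridized, per the labels, with biotin-labelled cRNA from MCF-7 cells. Per the design text, cells were kept overnight in serum-free medium and then left untreated or stimulated with IGF-I for 3 or 24 h. The recorded IGF-I dose was 8 nM, also given as 50 ng/ml, for all treated arrays. The value column holds intensity on a linear scale as deposited by the authors. The software and the normalization upstream of these values are not given in the sources used here. The unit was read from the values themselves: every array held only positive intensities with a lowest value of 3.71, shared by 3.49 to 4.21 percent of the probe sets on each array. No raw image files and no detection calls were analysed here.

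Arrays were grouped by the group and replicate number in their titles. One field of the labels describes cells sorted from primary tumours, whereas the title, the source field and the design text all describe treated MCF-7 cells. The grouping followed the latter. The RNA extraction kit also differs between the label protocol and the design text. The design text gives triplicates, while the 3 h control group analysed here held 2 arrays. The replicate numbers carry no stated pairing between groups, so no pairing term entered the model.

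Probe sets were assigned to genes through the annotation table provided for the platform and a RefSeq gene table. Of 22277 probe sets, 62 were chip controls, 19064 carried a single gene symbol, 1043 carried several symbols and 2108 carried none or none in the gene table. Of the assigned probe sets, 19052 were matched through a gene identifier and the rest through the symbol. This gave 11960 genes, 4312 of them with more than 1 probe set. For such genes the probe set with the highest mean over all arrays was used, a choice that does not look at the groups.

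Intensities under 8.08, the 10th percentile of the whole table, were raised to that floor before the log2 transformation, giving a lowest log2 value of 3.01. Where every array of a group sat at the floor, the fold change is given as a minimum. The array medians differed by 0.11 on the log2 scale, above the limit of 0.1 set beforehand, so the arrays were quantile normalized.

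The model fitted 1 mean per group (control 3 h, IGF-I 3 h, control 24 h, IGF-I 24 h) with limma, leaving 7 residual degrees of freedom, and used moderated t tests from its empirical Bayes step, which added 1.58 prior degrees of freedom. The 4 contrasts were IGF-I against control at 3 h, IGF-I against control at 24 h, the difference between these effects, and control at 24 h against control at 3 h. P-values were adjusted with the Benjamini-Hochberg method over all 11960 genes of a contrast. A gene was called when its adjusted p lay below 0.05, and the adjusted p values in the text are limma values of this kind unless a list test is named. Standard errors are the moderated ones. Higher and lower refer to the IGF-I arrays against the control arrays of the same time, and to 24 h against 3 h for the control arrays.

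The 22 gene lists, 17 of responses and 5 of cell types, were written from general knowledge before the data were examined. Some lists share members, so their counts are not separate. Examples are INSR and IRS2 (FOXO and insulin lists), ERBB3 (FOXO and luminal lists), and FOSL1 and IER3 (immediate early and ERK lists). Each was tested with the competitive camera test at its preset correlation of 0.01, adjusted over the 22 lists of a contrast. The counts adjusted over the list alone applied the Benjamini-Hochberg step to the measured members of 1 list only. Each list was also tested with camera at an estimated correlation and with the rotation test fry. Named genes followed a rule written with the lists: for each IGF-I comparison the 6 largest called rises and the 6 largest called falls in which every IGF-I array lay beyond every control array, the largest called members of each response list in either direction (or, where none was called, the member with the smallest p), and IGF1R, INSR, IRS1, IRS2, ESR1, PGR, CCND1 and MYC in any case. For each cell-type list these were the called members and the member with the highest level, and for the difference and the control contrast the 5 largest called changes in each direction. Further list members are named as examples and were chosen after their values were seen. List levels per group were means over members of gene-centred log2 values.

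Alternatives covered the values as deposited, median centring, no floor, a floor at the 25th percentile, removal of the dimmest genes by mean level (leaving 7973), all 22215 probe sets tested singly, the mean of a gene's probe sets, an intensity trend in the prior, array weights, the replicate number as a block, each array left out in turn, only the arrays of 1 time, an absolute log2 change of at least 1, and an adjusted p below 0.01. Several alternatives were chosen after the data were seen: a covariate from the 3'/5' signal ratios of the chip's control probe sets, the removal of both 24 h control arrays whose spike-in signals stood apart, and some additional settings for the lists. The families of genes in the closing observations and the tests of the array axis, of a weak array and of whether only the control arrays moved were likewise chosen after the results were seen. Regrouping tests split the 24 h arrays in every other way into groups of 3.

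The model was tested on simulated values with the gene means and the spread of the real table and with known changes placed in them. Of 100 genes given a log2 change of 1, 65 percent were called in the 3 h contrast, 71 percent at 24 h, 34 percent in the difference and 61 percent in the control contrast. At a log2 change of 2 the shares were 86, 92, 83 and 91 percent. In the same order, 165, 173, 128 and 162 genes were called in all, and 14, 10, 11 and 10 of them carried no placed change. In every contrast this share of false calls lay above the threshold set for the adjusted p. With no change placed, no gene was called, and the single list shifted was the single list called. The simulated genes were drawn independently of one another, so the list result does not cover lists with correlated members.

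The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.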

Results

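MCF-7 cells, an oestrogen-receptor-positive breast cancer line, were compared with and without IGF-I after an overnight incubation in serum-free medium. The 11 arrays comprised 2 controls and 3 IGF-I arrays at 3 h, and 3 controls and 3 IGF-I arrays at 24 h, which the labels call biological replicates. This array number limits the precision, most of all for contrasts that use the 3 h controls, where leaving out 1 array leaves a single one whose spread is assumed to equal that of the other groups. No detection calls were used, so a low level is not read as absence. Changes are log2 values, given with the standard error where 2 numbers are joined by ±, and genes are said to have risen or fallen only where they were called. The signal ratio of the 3' and 5' control probe sets for ACTB was 1.46 ± 0.11 (SD) in the 3 h controls, 1.34 ± 0.20 with IGF-I at 3 h, 1.56 ± 0.25 in the 24 h controls and 1.34 ± 0.38 with IGF-I at 24 h, and the group means for GAPDH were 0.910, 0.951, 0.976 and 0.989 in that order. For ISGF3A it was 7.14 ± 1.48 in the 3 h controls, 13.8 ± 10.2 with IGF-I at 3 h, 11.5 ± 2.28 in the 24 h controls and 16.6 ± 13.7 with IGF-I at 24 h.

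Probe-set intensities of cell-type markers were ranked over all 11 arrays. Intensities of different probe sets do not rank expression across genes, so no cell identity is drawn from them. Luminal markers, such as the keratins of simple epithelia and the oestrogen receptor, had a median intensity at percentile 98.2 of all genes, with 12 of 14 above the 90th. KRT18 lay at percentile 99.99. Median intensities were at percentile 17.0 for the 7 basal or mesenchymal markers, 27.6 for the 7 fibroblast markers, 28.2 for the 7 blood cell markers and 8.32 for the 4 endothelial markers. Among the leading markers of each cell type, KRT18, CD44, COL1A1, CD3D and PECAM1 were not called at either time: the changes were 0.12, -0.04, 0.61, 0.02 and 0.08 at 3 h and -0.04, -0.21, 0.54, -0.35 and 0.21 at 24 h. These values are from the brightest probe set, and at 24 h 3 of the 7 other probe sets of CD44 were called lower.

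**Figure D1:**
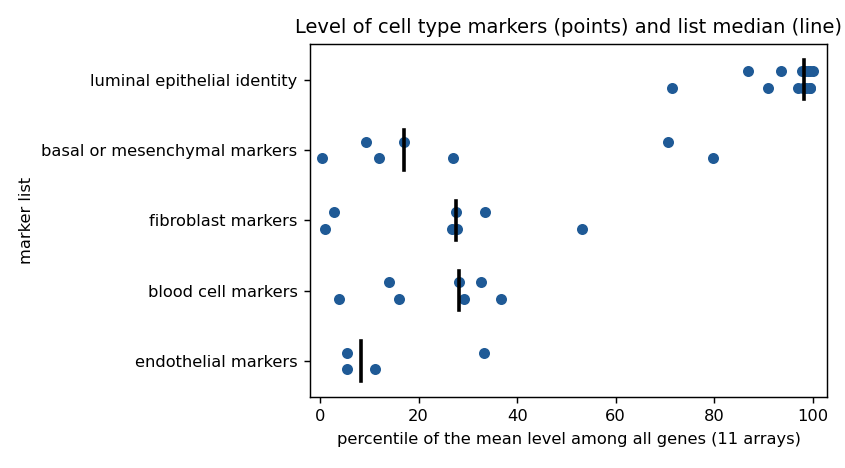
Mean probe-set intensity over all 11 arrays of each marker gene (points) and the list median (line) in 5 cell-type lists, as a percentile of all 11960 genes. The 14 luminal markers have a median of 98.2, and the other 4 lists have medians from 8.32 to 28.2. Intensities of different probe sets do not rank expression across genes.

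Within 3 h of IGF-I, the cells raised transcripts for building cell mass and for entering S phase, and lowered transcripts of the FOXO-induced list. The rising set covered amino acid transport and tRNA charging, sterol and fatty acid synthesis, ribosome assembly, the replication machinery and the ERK phosphatase genes DUSP4 and DUSP6. The falling set included FOXO targets, the insulin receptor gene and adaptor genes of its pathway, autophagy genes and mitotic genes. Both INSR and IRS2 belong to the FOXO list as well as to the insulin list. The calls of the fatty acid list (adjusted p = 0.060 with an estimated correlation) and of the insulin and mitosis lists (adjusted p = 0.18 each with an estimated correlation) ended in that test. The change was broad: 1167 genes rose and 1044 fell, together 18.5 percent of the 11960 tested. Rises made up 52.8 percent of these calls, 48.8 percent as deposited and 55.3 percent with median centring, so the excess of rises depends on the scaling. Changes of at least 1 on the log2 scale were seen in 213 genes upward and 196 downward.

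CHAC1, which degrades glutathione and is induced through ATF4, had the largest called rise at 3 h, at least 8.99-fold from controls that were all at the floor (3.17 ± 0.31, adjusted p = 0.00034). The cystine transporter gene SLC7A11 rose by 2.10 ± 0.17, and LRP8, which encodes a lipoprotein receptor, by 2.63 ± 0.51. FHL2 (2.07 ± 0.12, a LIM-domain cofactor), CORO1A (2.01 ± 0.19, an actin-binding coronin) and LAD1 (1.99 ± 0.14, an anchoring filament protein) followed. The deepest falls were in STON1 (-2.99 ± 0.21, an endocytic adaptor), N4BP2L1 (-2.53 ± 0.15) and TSPAN12 (-2.38 ± 0.19, a tetraspanin). They were followed by KCNJ8 (-2.24 ± 0.20, a potassium channel subunit), HBP1 (-2.20 ± 0.10, a repressor of cell-cycle genes) and BLNK (-2.01 ± 0.10, an adaptor protein). By the rule for naming them, only genes in which every IGF-I array lay beyond both control arrays were ranked here. That separation is therefore no further result.

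**Figure D2:**
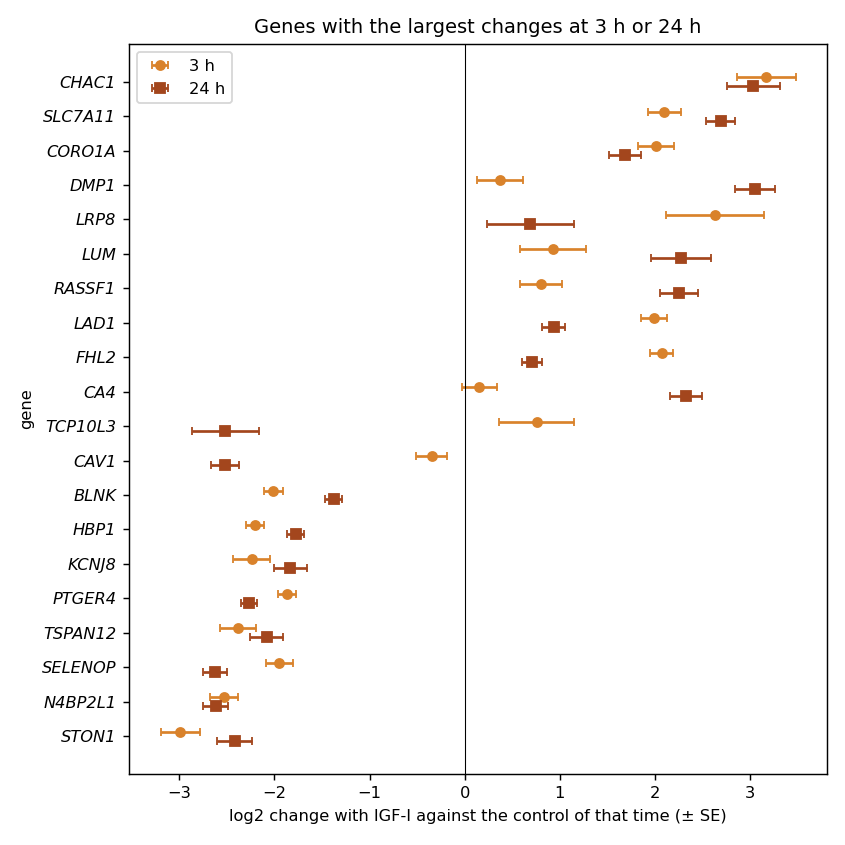
Log2 change with IGF-I (points, bars for the standard error) at 3 h and 24 h for the 20 genes with the largest called changes at either time. Only genes in which every IGF-I array of that time lay beyond every control array were ranked. STON1 and N4BP2L1 lie at -2.99 and -2.53 at 3 h and at -2.42 and -2.62 at 24 h, while DMP1 and CA4 stand out only at 24 h.

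Transcripts of lists for the supply of building blocks rose at 3 h. Of 24 amino acid supply and tRNA charging genes, 16 were higher and 0 lower (19 and 0 adjusted over the list alone), with a mean change of 0.74 (camera adjusted p = 5.2e-12). Beside CHAC1 and SLC7A11 these included SLC7A5 (1.23 ± 0.16), which imports large neutral amino acids, the tRNA synthetase genes YARS1 (1.19 ± 0.11) and GARS1 (1.10 ± 0.17), and ASNS (1.01 ± 0.10). Genes of the cholesterol synthesis and uptake list followed the same direction, 12 of 17 higher and 0 lower (12 and 0 adjusted over the list alone, mean 0.71, adjusted p = 2.3e-08). MVD (1.96 ± 0.23) and HMGCS1 (1.63 ± 0.09) of the mevalonate pathway rose most. Only 17 of the 24 members of this list were measured. Its uptake genes LDLR and PCSK9, and also HMGCR, had no probe set with a single gene symbol. The values of this list therefore describe synthesis and not uptake. In fatty acid synthesis 6 of 9 genes were higher and 0 lower (8 and 0 adjusted over the list alone, mean 0.69, adjusted p = 9.0e-06, and adjusted p = 0.060 with an estimated correlation). Among them were ELOVL6 (1.05 ± 0.09), which elongates fatty acids, and ACACA (0.83 ± 0.22), which supplies malonyl-CoA. Of 14 glycolysis and hypoxia-type genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.18 with an estimated correlation). Here VEGFA rose (1.60 ± 0.15) and NDRG1, a stress-responsive gene, fell (-1.70 ± 0.18).

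Ribosome biogenesis and heat shock genes rose at 3 h. In ribosome biogenesis 15 of 22 genes were higher and 0 lower (16 and 0 adjusted over the list alone, mean 0.69, adjusted p = 3.7e-11). They included RRP9 (1.38 ± 0.11), which acts in pre-rRNA processing, the helicase gene DDX21 (1.35 ± 0.15) and MYBBP1A (1.26 ± 0.09). Heat shock genes rose in 5 of 7 with 0 lower (5 and 0 adjusted over the list alone, mean 0.35, adjusted p = 0.00059), with HSPH1 at 0.69 ± 0.07 and HSPE1 at 0.53 ± 0.10. Endoplasmic reticulum chaperones went both ways, 5 of 14 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.23). SDF2L1 (1.02 ± 0.12) and CRELD2 (0.83 ± 0.09) rose, while SEL1L (-0.66 ± 0.08), part of the machinery that clears misfolded proteins, fell.

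Replication genes rose at 3 h, and no gene of the mitosis list did. Of 33 DNA replication and G1/S genes, 25 were higher and 0 lower (27 and 0 adjusted over the list alone, mean 0.63, adjusted p = 3.1e-14). The initiation factor gene MCM10 (1.46 ± 0.08) and CCNE1 (1.37 ± 0.14), which encodes cyclin E, rose most among them. Mitotic genes were 0 of 29 higher and 10 lower (1 and 13 adjusted over the list alone, mean -0.33, adjusted p = 1.1e-05, and adjusted p = 0.18 with an estimated correlation). Here HMMR (-0.92 ± 0.12) and ASPM (-0.82 ± 0.12), both spindle proteins, had fallen most. DNA repair genes rose in 3 of 13 with 0 lower (7 and 0 adjusted over the list alone, mean 0.38, adjusted p = 0.011, and adjusted p = 0.18 with an estimated correlation). EXO1 stood at 0.81 ± 0.11 and BRCA1 at 0.79 ± 0.19.

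Signalling genes downstream of the receptor split by pathway at 3 h. ERK output and feedback genes were 4 of 15 higher and 0 lower (5 and 2 adjusted over the list alone, mean 0.53, adjusted p = 0.0089). DUSP4 (1.56 ± 0.13), SPRY4 (1.43 ± 0.34) and DUSP6 (1.26 ± 0.12) all encode proteins that dampen ERK signalling. Immediate early genes went both ways, 5 of 20 higher and 3 lower (6 and 4 adjusted over the list alone, adjusted p = 0.093). EGR3 (1.93 ± 0.11) and EGR1 (1.30 ± 0.17) were raised at 3 h, while FOS (-1.05 ± 0.26) and MYC (-0.61 ± 0.16) lay below control. FOXO-induced genes fell as a group, 1 of 17 higher and 12 lower (1 and 12 adjusted over the list alone, mean -0.79, adjusted p = 1.2e-08). CITED2 (-1.87 ± 0.15), IRS2 (-1.64 ± 0.07), PIK3IP1 (-1.47 ± 0.13) and the growth factor receptor gene ERBB3 (-1.26 ± 0.11) were among them, with GADD45A (0.53 ± 0.13) as the exception.

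Components of the insulin and IGF pathway were 1 of 18 higher and 5 lower at 3 h (1 and 6 adjusted over the list alone, mean -0.30, adjusted p = 0.013, and adjusted p = 0.18 with an estimated correlation). INSR (-0.86 ± 0.22), IRS1 (-0.61 ± 0.10) and the inhibitory adaptor gene GRB14 (-0.88 ± 0.16) fell, while GRB10, which encodes a related adaptor, rose by 0.56 ± 0.11. IGF1R was not called (-0.19 ± 0.38, adjusted p = 0.81), and neither was CCND1 (0.41 ± 0.16, adjusted p = 0.12), although its other probe set was called higher. Autophagy genes were 0 of 12 higher and 4 lower (0 and 5 adjusted over the list alone, mean -0.50, adjusted p = 0.00073), with GABARAPL1 (-1.75 ± 0.44) and ATG14 (-1.25 ± 0.10) lowest.

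PGR (-1.28 ± 0.19, adjusted p = 0.0027) and ESR1 (-0.30 ± 0.08, adjusted p = 0.033) were lower at 3 h. The call of ESR1 ended under 12 settings, among them the deposited scaling, median centring, no floor and the mean of its probe sets. Of 17 oestrogen-induced genes 3 were higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.80). EGR3 was among the former and PGR and MYB (-0.92 ± 0.09) among the latter. Luminal identity genes were 1 of 14 higher and 3 lower (1 and 4 adjusted over the list alone, adjusted p = 0.093). KRT19 rose by 0.31 ± 0.08, and FOXA1, a pioneer factor for the oestrogen receptor, stood at -0.40 ± 0.10. Of 10 interferon-stimulated genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.80), namely ISG15 (0.79 ± 0.18). No member was called among 7 basal, 7 fibroblast, 7 blood cell and 4 endothelial markers, also adjusted over the list alone (adjusted p = 0.84, 0.11, 0.39 and 0.96).

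With an estimated correlation between list members, the calls at 3 h held for the ERK, FOXO, cholesterol, amino acid, ribosome biogenesis, DNA replication, heat shock and autophagy lists. Their camera adjusted p values were then 0.0498, 0.0051, 0.0051, 0.0082, 0.0082, 0.012, 0.024 and 0.046 in that order. The ERK and autophagy lists thus lay close to the threshold. Without control replicate 1 or 2 the count of called genes was 1080 or 1177. The calls of ACACA, BRCA1, ERBB3, ESR1, FOS, FOXA1, GABARAPL1, GADD45A, GRB10, GRB14, HSPE1, INSR, ISG15, KRT19, LRP8, MYC, SEL1L, SPRY4 and VEGFA ended under at least 1 alternative.

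After 24 h of IGF-I, mitotic and replication genes stood above the 24 h controls, in which both lists had fallen since 3 h (means -0.97 and -0.36). The amino acid genes stood further above control than at 3 h. Ribosome biogenesis was no longer called, against controls in which it had risen since 3 h (mean 0.42). Sterol genes were less raised than at 3 h. FOXO targets and the insulin receptor stayed low. In total 1337 genes were higher and 1475 lower, 23.5 percent of all genes, of which 250 rose and 187 fell by at least 1 on the log2 scale. The higher ones made up 47.5 percent of the calls, but 50.7 percent as deposited and 53.6 percent with median centring. Which direction held more calls thus depends on the scaling.

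DMP1, an extracellular matrix protein of mineralized tissue, rose at least 8.29-fold from controls all at the floor (3.05 ± 0.21), although its other probe set changed in the opposite direction without being called. CHAC1 (3.03 ± 0.28), SLC7A11 (2.69 ± 0.15), CA4 (2.33 ± 0.17, a carbonic anhydrase), LUM (2.27 ± 0.31, a matrix proteoglycan) and RASSF1 (2.25 ± 0.20, a tumour suppressor of the Ras association family) followed. The largest falls were in SELENOP (-2.63 ± 0.13, a selenium transport protein), N4BP2L1 (-2.62 ± 0.13) and CAV1 (-2.52 ± 0.15, the main protein of caveolae). TCP10L3 (-2.52 ± 0.35, with 2 of the IGF-I arrays at the floor), STON1 (-2.42 ± 0.18) and PTGER4 (-2.27 ± 0.08, a prostaglandin receptor) came next. As at 3 h, only genes whose IGF-I arrays all lay beyond all control arrays were ranked.

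Mitotic genes were raised at 24 h, with 28 of 29 higher and 0 lower (29 and 0 adjusted over the list alone, mean 1.09, camera adjusted p = 6.7e-24). The kinetochore genes NDC80 (1.80 ± 0.11) and CENPE (1.79 ± 0.17) led them, and the proliferation marker MKI67 (1.69 ± 0.11) and the mitotic kinase gene PLK1 (1.62 ± 0.13) were close. In DNA replication and G1/S 25 of 33 were higher and 1 lower (28 and 1 adjusted over the list alone, mean 0.72, adjusted p = 1.6e-16). CDC45 (1.80 ± 0.11), a helicase component, and MCM10 (1.50 ± 0.07) rose most, whereas CCNE1, up at 3 h, was now below control (-0.57 ± 0.12). DNA repair genes were higher in 9 of 13 and lower in 1 (9 and 2 adjusted over the list alone, mean 0.68, adjusted p = 0.00044, and adjusted p = 0.13 with an estimated correlation). XRCC3 (1.87 ± 0.31) and BRCA1 (1.40 ± 0.17) rose, and MSH6 (-0.37 ± 0.11) fell.

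Amino acid supply genes remained high at 24 h. Of 24 amino acid supply and tRNA charging genes, 22 were higher and 0 lower (23 and 0 adjusted over the list alone, mean 1.16, adjusted p = 2.4e-20). They included ASNS (1.78 ± 0.09) and the serine pathway genes PSPH (1.38 ± 0.10), SHMT2 (1.28 ± 0.09) and PHGDH (1.16 ± 0.11). Fatty acid synthesis genes were higher in 7 of 9 and lower in 0 (7 and 0 adjusted over the list alone, mean 0.72, adjusted p = 7.1e-05, and adjusted p = 0.12 with an estimated correlation). The desaturase gene SCD (1.38 ± 0.07) and its regulator SREBF1 (1.35 ± 0.16) led them. Cholesterol genes were 7 of 17 higher and 1 lower (9 and 2 adjusted over the list alone, mean 0.25, adjusted p = 0.016, and adjusted p = 0.093 with an estimated correlation). MVD (1.07 ± 0.21) and FDPS (0.95 ± 0.06) rose and MVK (-0.48 ± 0.14) fell. Among 14 glycolysis and hypoxia-type genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.080). VEGFA stood at 1.58 ± 0.13 and NDRG1 at -1.44 ± 0.16.

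Ribosome biogenesis was not called at 24 h, 2 of 22 higher and 1 lower (2 and 1 adjusted over the list alone, mean 0.03, adjusted p = 0.87). The called genes were RRP12 (0.76 ± 0.15), TSR1 (0.38 ± 0.09) and NPM1 (-0.22 ± 0.06). Heat shock genes were 0 of 7 higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.46), the co-chaperone gene BAG3 (-0.63 ± 0.09). Among the endoplasmic reticulum chaperones 5 of 14 were higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.080). CALR (0.52 ± 0.13) and CRELD2 (0.51 ± 0.08) rose and DNAJB9 (-0.44 ± 0.09) fell. Autophagy genes were 0 of 12 higher and 4 lower (0 and 5 adjusted over the list alone, adjusted p = 0.099), through ATG14 (-1.19 ± 0.09) and WIPI1 (-1.07 ± 0.11), both acting in autophagosome formation.

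FOXO-induced genes were still low at 24 h, 2 of 17 higher and 9 lower (2 and 9 adjusted over the list alone, mean -0.43, adjusted p = 0.0031). INSR (-1.68 ± 0.20, adjusted p = 0.00054) and IRS2 (-1.30 ± 0.06, adjusted p = 1.5e-05) fell furthest, ERBB3 stood at -0.57 ± 0.10, and GADD45A rose by 0.93 ± 0.12. In the insulin and IGF list 3 of 18 were higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.72). IGFBP2, which encodes a binding protein for IGF-I, rose (0.65 ± 0.17) and IRS1 fell (-0.30 ± 0.09). IGF1R (-0.11 ± 0.34, adjusted p = 0.88) was not called. ERK output genes were 4 of 15 higher and 2 lower (4 and 2 adjusted over the list alone, adjusted p = 0.15). The phosphatase genes DUSP6 (0.91 ± 0.11) and DUSP5 (0.78 ± 0.12) rose and SPRY1 (-0.72 ± 0.16) fell. CCND1 was not called (-0.13 ± 0.14, adjusted p = 0.57), while its other probe set was called in the opposite direction. Immediate early genes were 5 of 20 higher and 3 lower (6 and 4 adjusted over the list alone, adjusted p = 0.41). ATF3 (1.53 ± 0.16) and EGR3 (0.68 ± 0.10) were up, and CCN2 (-1.38 ± 0.23) and MYC (-0.61 ± 0.14) down.

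ESR1 was called lower at 24 h (-0.32 ± 0.07, adjusted p = 0.013). This call ended under 4 settings, namely the deposited scaling, median centring, the mean of its probe sets and leaving out both 24 h controls of unusual spike-ins, and 3 of its 8 other probe sets shared the sign. PGR was no longer called (0.19 ± 0.17, adjusted p = 0.50). Oestrogen-induced genes were 2 of 17 higher and 2 lower (2 and 2 adjusted over the list alone, adjusted p = 0.997), with EGR3 up and MYB (-0.84 ± 0.08) and XBP1 (-0.34 ± 0.06) down. Luminal identity genes were 0 of 14 higher and 4 lower (0 and 5 adjusted over the list alone, mean -0.21, adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation). SPDEF (-0.57 ± 0.12), a luminal transcription factor, fell most. Of 10 interferon-stimulated genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone, adjusted p = 0.14), namely IFI27 (1.20 ± 0.24) and ISG15 (0.79 ± 0.16). Among basal or mesenchymal markers 0 of 7 were higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.74), the filament gene VIM (-0.65 ± 0.15). Fibroblast markers had 1 of 7 higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.31), which was LUM. Of 7 blood cell and 4 endothelial markers none was called, also adjusted over the list alone (adjusted p = 0.87 and 0.31).

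At 24 h the calls that held with an estimated correlation were those of the FOXO, amino acid, DNA replication and mitosis lists. Their camera adjusted p values were then 0.049, 0.0065, 0.021 and 0.031 in that order. The luminal identity call also ended under the deposited scaling (mean -0.10) and the median scaling (mean -0.08). Without both control arrays whose spike-ins stood apart the count was 1414. Calls of CALR, CCN2, CCNE1, ERBB3, ESR1, IGFBP2, IRS1, MSH6, MVD, MVK, MYC, NPM1, RRP12, SPDEF, SPRY1, TSR1, VIM, XBP1 and XRCC3 ended under at least 1 alternative, and the mean of a gene's probe sets turned ESR1 to 0.012 and MVK to 0.45, neither called.

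Early and late responses shared a core and, among the lists, differed most in mitosis. Of all genes, 533 rose at both times (130.5 expected by chance from the margins) and 601 fell at both (128.8 expected). Fewer than expected went from higher to lower (69, 143.9 expected) or from lower to higher (44, 116.7 expected). These expectations treat the calls of both times as independent, although both contrasts share 1 estimate of each gene's spread. Across genes, which are not independent of one another, the changes at the different times correlated with r = 0.42 (Spearman rho = 0.38). The shared core held SLC7A11, CHAC1, MCM10, VEGFA and FDPS upward and IRS2, INSR, STON1, N4BP2L1, CITED2 and ATG14 downward. At 3 h, however, 0 of the 3 other probe sets of VEGFA were called, and its call ended with the mean of its probe sets. The 3 h call of INSR ended under 5 settings. The genes that turned from lower to higher included all the mitosis genes lowered at 3 h, HMMR, ASPM, TOP2A, CCNB2, NDC80, KIF11, KIF20A, CENPF, TPX2 and DLGAP5.

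**Figure D3:**
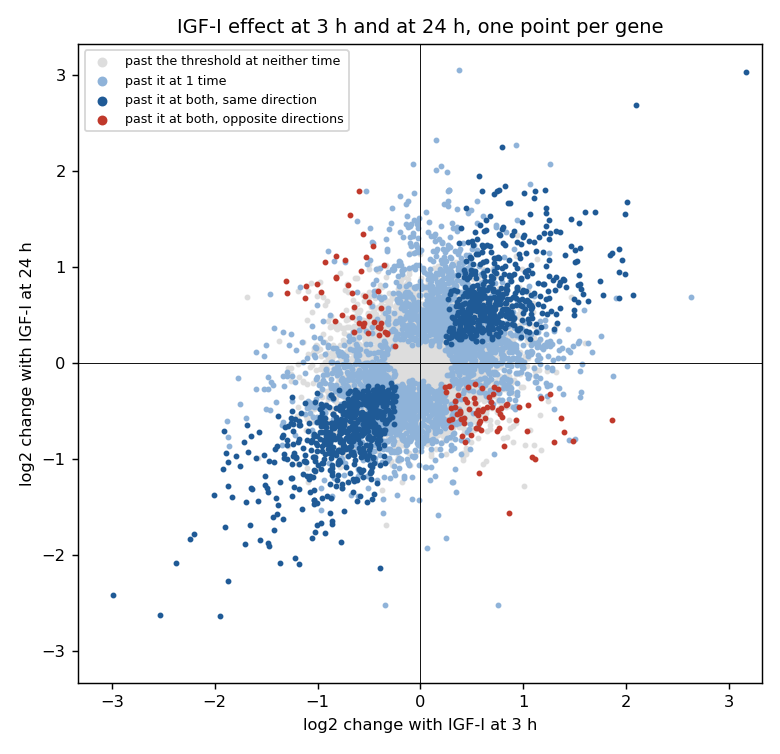
Log2 change with IGF-I at 3 h (horizontal) against 24 h (vertical) for all 11960 genes (points), coloured by whether a gene was called at neither time, 1 time or both. The changes correlate with r = 0.42, and among genes called at both times 69 went from higher to lower and 44 from lower to higher.

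When the difference between the effects was tested directly, 363 genes had a higher effect at 24 h and 486 a lower one, 7.10 percent of all genes, with 148 and 152 of them differing by at least 1. The higher ones made up 42.8 percent of these calls, but 51.1 percent with the values as deposited, so the excess of lower calls depends on the scaling. Mitosis genes gained most, 26 of 29 with 0 lower (29 and 0 adjusted over the list alone, mean 1.42, adjusted p = 3.1e-36). Amino acid genes followed with 6 of 24 higher and 0 lower (13 and 0 adjusted over the list alone, mean 0.42, adjusted p = 6.1e-08). FOXO-induced genes were less lowered at 24 h, 7 of 17 higher and 0 lower (11 and 1 adjusted over the list alone, mean 0.36, adjusted p = 9.2e-06). TXNIP (1.12 ± 0.12), which encodes an inhibitor of glucose uptake, was one of them. Losses were seen in ribosome biogenesis, with 0 of 22 higher and 11 lower (0 and 15 adjusted over the list alone, mean -0.65, adjusted p = 1.7e-10). In the controls this list rose from 3 h to 24 h (mean 0.42). Cholesterol synthesis had 0 of 17 higher and 4 lower (0 and 8 adjusted over the list alone, mean -0.46, adjusted p = 8.4e-05). Heat shock genes had 0 of 7 higher and 3 lower (0 and 3 adjusted over the list alone, mean -0.34, adjusted p = 0.0028). All of these 6 list calls held with an estimated correlation, at camera adjusted p from 0.010 (mitosis) to 0.038 (heat shock).

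The single genes with the largest differences were DMP1 (2.68 ± 0.32), NDC80 (2.39 ± 0.16), CENPE (2.32 ± 0.26), ABCA12 (2.22 ± 0.15, a lipid transporter) and SYNE1 (2.18 ± 0.48, a nuclear envelope protein) on the side gaining at 24 h. TCP10L3 (-3.28 ± 0.53), TMEM158 (-2.46 ± 0.22), PLEKHO2 (-2.41 ± 0.30), MAP6D1 (-2.29 ± 0.15, a microtubule-associated protein) and ICAM2 (-2.29 ± 0.55, an adhesion molecule) lay on the other. PGR belonged to the genes whose effect differed (1.47 ± 0.26, adjusted p = 0.013), being called lower at 3 h and not at 24 h. The effects on EGR1 (-1.77 ± 0.23) and CCNE1 (-1.94 ± 0.18) were lower at 24 h than at 3 h.

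The other 16 lists were not called for the difference. DNA replication had 7 of 33 higher and 2 lower (7 and 4 adjusted over the list alone, adjusted p = 0.26), and DNA repair 2 of 13 higher and 2 lower (3 and 2 adjusted over the list alone, adjusted p = 0.053). Insulin and IGF components had 1 of 18 higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.086), and ERK output 0 of 15 higher and 1 lower (0 and 1 adjusted over the list alone, adjusted p = 0.21). Among immediate early genes 1 of 20 was higher and 2 lower (2 and 4 adjusted over the list alone, adjusted p = 0.42). For autophagy 1 of 12 was higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.40). An adjusted p of 0.98 was shared by several lists. These were fatty acid synthesis with 1 of 9 higher and 1 lower (1 and 3 adjusted over the list alone) and glycolysis with 0 of 14 higher and 1 lower (1 and 2 adjusted over the list alone). Oestrogen-induced genes with 2 of 17 higher and 2 lower, endoplasmic reticulum chaperones with 1 of 14 and 1, luminal genes with 1 of 14 and 1, and basal and fibroblast markers with 0 of 7 each belonged to them too, with the same counts adjusted over the list alone. Of the rest, interferon-stimulated genes had 0 of 10 called (adjusted p = 0.36) and endothelial markers 0 of 4 (adjusted p = 0.42). Blood cell markers had 0 of 7 higher and 1 lower, CD14 at -1.32 ± 0.32 (adjusted p = 0.45), again with the same counts adjusted over the list alone. Without control replicate 1 or 2 of 3 h, or control replicate 3 of 24 h, the count of differing genes was 355, 484 or 504 in place of 849. It was 1551 with array weights and 346 without both 24 h controls of unusual spike-ins, and the calls of ICAM2, SYNE1 and TCP10L3 ended under 15, 9 and 2 settings.

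Without IGF-I, cell cycle genes were lower in the 24 h controls than in the 3 h controls. With these groups, time in serum-free medium cannot be told apart from time in culture or handling. From 3 h to 24 h the control cells lost mitotic and replication transcripts and gained immediate early, ERK output and ribosome biogenesis transcripts. Of all genes, 205 rose and 247 fell, 3.78 percent of those tested, with 31 and 58 of them changing by at least 1.

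Mitosis genes fell in 26 of 29 with 0 higher (0 higher and 29 lower adjusted over the list alone, mean -0.97, adjusted p = 1.2e-38), among them CENPE (-1.52 ± 0.19) and NDC80 (-1.49 ± 0.12). Outside the list DEPDC1 (-1.54 ± 0.28), KIF18A (-1.40 ± 0.19) and the mitotic phosphatase gene CDC25C (-1.38 ± 0.18) fell as far. DNA replication genes were lower in 6 of 33 with 0 higher (0 and 13 adjusted over the list alone, mean -0.36, adjusted p = 2.8e-12). DNA repair genes were lower in 4 of 13 with 0 higher (0 and 4 adjusted over the list alone, mean -0.45, adjusted p = 0.00020, and adjusted p = 0.11 with an estimated correlation). Sterol genes were 0 of 17 higher and 2 lower (0 and 3 adjusted over the list alone, mean -0.21, adjusted p = 0.00035). For fatty acid synthesis 0 of 9 were higher and 1 lower (0 and 2 adjusted over the list alone, mean -0.38, adjusted p = 0.00057, and adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes were 0 of 10 higher and 2 lower (0 and 3 adjusted over the list alone, mean -0.43, adjusted p = 0.0033, and adjusted p = 0.20 with an estimated correlation).

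Ribosome biogenesis genes were higher in 8 of 22 with 0 lower (14 and 0 adjusted over the list alone, mean 0.42, adjusted p = 1.3e-10). Immediate early genes were higher in 5 of 20 with 0 lower (6 and 0 adjusted over the list alone, mean 0.39, adjusted p = 2.3e-05), and ERK output genes in 2 of 15 with 0 lower (4 and 0 adjusted over the list alone, mean 0.42, adjusted p = 0.00059). Amino acid genes were higher in 4 of 24 with 0 lower (11 and 2 adjusted over the list alone, mean 0.23, adjusted p = 0.00090, and adjusted p = 0.12 with an estimated correlation). The largest single rises were in CHAC1 (1.71 ± 0.31, at least 3.27-fold) and the DHFR pseudogene DHFRP3 (1.41 ± 0.27, at least 2.65-fold), both at the floor in the 3 h controls. KCNK15 (1.57 ± 0.17, a potassium channel), FJX1 (1.43 ± 0.13) and TNS3 (1.39 ± 0.23, a focal adhesion protein) came next. TFF3, a secreted luminal protein, rose by 0.56 ± 0.09.

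The remaining lists were not called in the controls over time. Insulin and IGF components had 0 of 18 higher and 1 lower (adjusted p = 0.92), luminal identity 1 of 14 higher and 0 lower (adjusted p = 0.18) and the FOXO list 0 of 17 called (adjusted p = 0.996). No member was called among 14 endoplasmic reticulum chaperones (adjusted p = 0.85), 7 heat shock genes and 12 autophagy genes (adjusted p = 0.69 each). The same was true of 7 basal (0.92), 7 fibroblast (0.33), 7 blood cell (0.85) and 4 endothelial markers (0.77). All these counts were the same adjusted over the list alone. Glycolysis genes had 1 of 14 higher and 0 lower (2 and 1 adjusted over the list alone, adjusted p = 0.92). Oestrogen-induced genes had 3 of 17 higher and 1 lower (3 and 2 adjusted over the list alone, adjusted p = 0.69). With an estimated correlation the calls of the mitosis, DNA replication, ribosome biogenesis, immediate early, ERK and cholesterol lists held. Their camera adjusted p values were then 0.016, 0.020, 0.016, 0.017, 0.020 and 0.020 in that order. Without control replicate 1 or 2 of 3 h, or control replicate 2 or 3 of 24 h, the count was 102, 163, 267 or 224 in place of 452. It was 1341 with array weights and 70 without both 24 h controls of unusual spike-ins, and of the genes named here only NDC80 and FJX1 stayed called under every alternative.

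**Figure D4:**
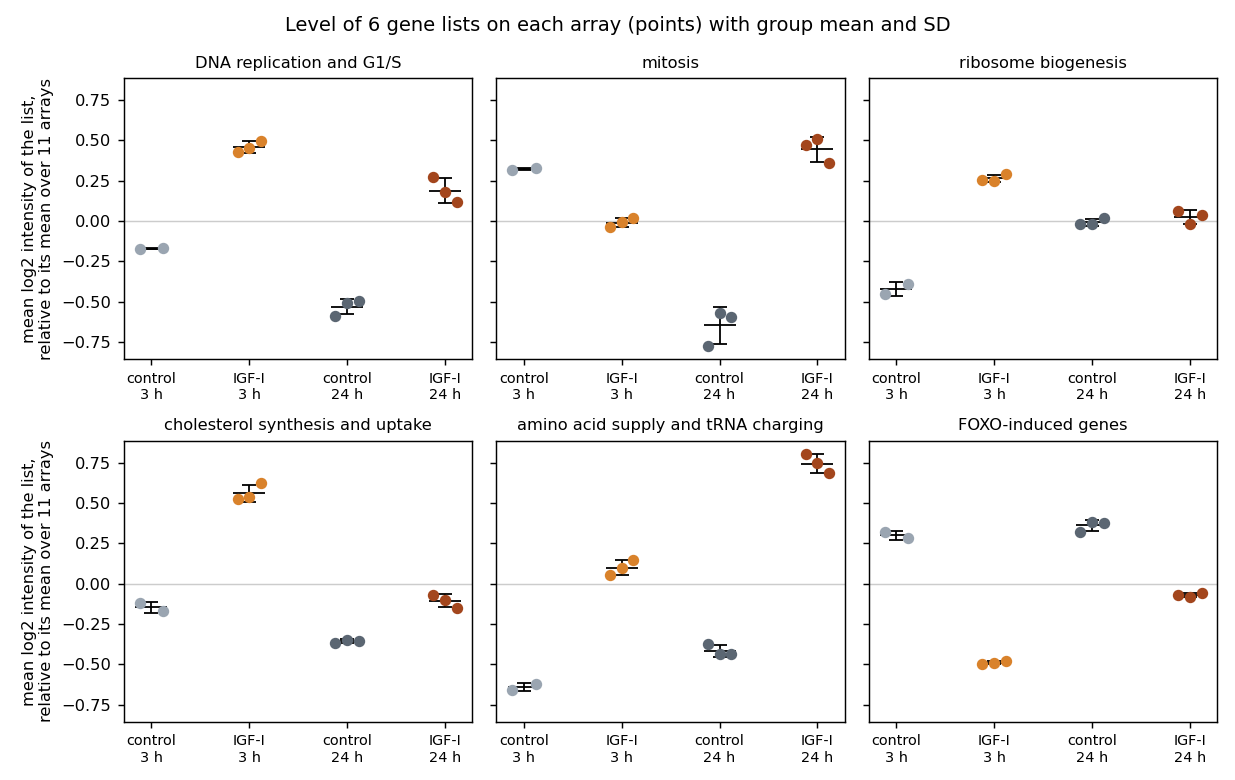
Mean gene-centred log2 level of 6 lists in each array (points) with the group mean and SD (lines) in control and IGF-I cells at 3 h and 24 h. The mitosis list stands at 0.32 and -0.01 at 3 h and at -0.65 and 0.44 at 24 h without and with IGF-I, while ribosome biogenesis stands at -0.42 and 0.26 at 3 h and at -0.01 and 0.03 at 24 h.

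Group levels placed these effects side by side. The mitosis list averaged 0.32 in the 3 h controls, -0.01 with IGF-I at 3 h, -0.65 in the 24 h controls and 0.44 with IGF-I at 24 h. DNA replication followed with -0.17, 0.46, -0.53 and 0.19 in the same order, and amino acid supply with -0.64, 0.10, -0.42 and 0.74. Cholesterol synthesis stood at -0.15, 0.56, -0.36 and -0.11, ribosome biogenesis at -0.42, 0.26, -0.01 and 0.03, and the FOXO list at 0.30, -0.49, 0.36 and -0.07. In some uncalled lists the median, the mean and the test differed in sign. This was seen for the oestrogen-induced genes at 3 h, at 24 h and in the difference, and for basal markers at 3 h and in the control contrast. It was also seen for insulin and IGF components at 24 h, fatty acid synthesis and glycolysis in the difference, and glycolysis and the FOXO list in the control contrast.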

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

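For the mitosis pattern, the tests of the 3'/5' covariate, of the median scaling and of whether only the control arrays moved were chosen after the data were seen. The genes and lists in this part drew attention because a direct limma test found that the IGF-I effect at 24 h differed from that at 3 h. Values are the 24 h effect minus the 3 h effect on the log2 scale, from 11 arrays.

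Mitosis genes showed the largest difference between times of the lists tested, a mean of 1.42 with 26 of 29 members called higher, and single genes moved with them: NDC80 by 2.39, CENPE by 2.32, HMMR by 1.98 and ASPM by 1.72. With the 3'/5' ratio as a covariate the mean was 1.43 (camera adjusted p = 7.1e-33), so a linear term of that ratio did not account for it. RNA integrity beyond this ratio was not tested. The lowest mean under the deposited and the median scaling was 1.45. As the array medians differed by only 0.11, a change of scaling could hardly have moved a mean of 1.42. A change of the control arrays alone is argued against by the IGF-I arrays, in which the list stood 0.45 higher at 24 h than at 3 h, against a sum of the SDs of 0.11. The control arrays made up the larger part of the difference, a fall of the list from 3 h to 24 h (mean -0.97). As a hypothesis for the smaller part only, cells that entered S phase after IGF-I may have reached mitosis by 24 h. DNA content was not measured, so this stays open.

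Other proliferation and growth genes differed as well. CDC45 gained 1.20 and RASSF1 1.45, while CCNE1 (-1.94) and the mismatch repair gene MSH6 (-0.77) lay lower. Amino acid supply gained 0.42 as a list. Ribosome biogenesis lost on average (-0.65), with RRP9 at -1.21 and DDX21 at -1.20. The control arrays made up the larger part of this loss. The list averaged -0.42 at 3 h and -0.01 at 24 h in the controls, and 0.26 and 0.03 with IGF-I.

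Sterol genes as a list stood at -0.46 and HMGCS1 at -1.42. In fatty acid synthesis SCD differed by 0.75 and ELOVL6 by -0.59. Heat shock genes averaged -0.34, with HSPH1 and HSPE1 at -0.53 each and BAG3 at -0.80. SDF2L1 lay at -0.68 and SEL1L at 0.54, and the autophagy gene WIPI1 at -0.81.

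Among the early signalling genes EGR1 differed by -1.77, EGR3 by -1.25 and DUSP4 by -0.79, while DUSP1 differed by 0.76 and neither the immediate early list (adjusted p = 0.42) nor the ERK list (adjusted p = 0.21) was called. The FOXO list differed by 0.36, ERBB3 by 0.69, PGR by 1.47 and BLNK by 0.64. KRT19 lay at -0.53, LAD1 at -1.06 and FHL2 at -1.36.

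The largest single differences outside the lists were DMP1 (2.68), ABCA12 (2.22), SYNE1 (2.18) and CA4 (2.17) on the gaining side. TCP10L3 (-3.28), TMEM158 (-2.46), PLEKHO2 (-2.41), MAP6D1 (-2.29), ICAM2 (-2.29) and CAV1 (-2.17) lay on the other. DMP1 in the 24 h controls and TCP10L3 in 2 IGF-I arrays of 24 h sat at the floor, so these values depend on it. No technical explanation was tested for these genes.

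Probe sets without a single gene name, 3151 in number and outside the gene comparisons, also responded: 302 were called at 3 h and 377 at 24 h. The largest changes among them were 1.94 and -2.13 at 3 h and 1.81 and -2.08 at 24 h.

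Other splits of the 6 arrays of 24 h were also tested with limma. Of the 10 splits into 3 and 3, the real one called 2812 genes and 1 split reached that number, the real one itself, with 0 as the highest count of the others. With 10 splits no share under 0.05 can be reached.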

How the results depend on the processing

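Of 129 named gene calls, 79 held under the processing settings run for single genes, which did not include the stricter thresholds or the fits of 1 time. The 3'/5' covariate, array weights, the variance trend and leaving out the dimmest genes ended 0 of them, and leaving out both 24 h controls of unusual spike-ins, chosen after the data were seen, ended 30. Leaving out control replicate 1 of 3 h ended 23, replicate 2 of 3 h 21, the replicate block 20 (among them FOS, MYC, FOXA1 and GABARAPL1 at 3 h and IGFBP2 at 24 h), and the mean of a gene's probe sets 13. That mean turned ESR1 at 24 h to 0.012 (adjusted p = 0.998) and MVK at 24 h to 0.45 (adjusted p = 0.37), because it gives weight to probe sets that the brightest one replaces elsewhere. Of values called under neither setting, 21 gene values and 68 list means changed sign.

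Called genes ranged, with 1 array left out, from 1080 (control replicate 1 of 3 h; 1177 without replicate 2) to 2302 at 3 h, 2072 to 2823 at 24 h, 355 to 875 for the difference (484 without control replicate 2 of 3 h, 504 without control replicate 3 of 24 h) and 102 to 470 for the control contrast (163 without control replicate 2 of 3 h, 267 and 224 without control replicates 2 and 3 of 24 h). A group reduced to 1 array was assumed to vary like the others. Without both 24 h controls the counts were 1414 at 24 h, 346 for the difference and 70 for the control contrast. Array weights gave 1551 for the difference and 1341 for the control contrast; the cause was not tested. A log2 change of at least 1 left 409, 437, 300 and 89 genes, and an adjusted p below 0.01 left 1109, 1578, 293 and 151, fewer by construction. Apart from the replicate block, the counts of genes in all other settings stayed within 1.5 times, and the share of higher calls moved by under 10 points with the scaling.

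The replicate block gave 1541 genes at 3 h, 2328 at 24 h, 382 for the difference and 137 for the control contrast, of which 1491, 2269, 380 and 137 were calls of the same direction without it. Arrays with the same number correlated from -0.21 to 0.11 over 15 pairs, and 3 of 11 arrays correlated best with their own number, so the numbers show no pairing.

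Lists called numbered 13 at 3 h and 8 with an estimated correlation, 8 at 24 h against 4 with an estimated correlation and 15 with fry, and 10 in the control contrast against 6 with an estimated correlation. In the lists whose calls ended, the estimated correlation lay above the preset 0.01, except for the cholesterol list at 24 h with 0.0027. Camera adjusted p values also rose in lists with an estimated correlation below the preset. At 3 h the FOXO list (-0.015) went from 1.2e-08 to 0.0051 and heat shock (-0.024) from 0.00059 to 0.024. A higher correlation alone thus does not account for the weaker results. The cause of these differences between tests was not tested. With 1 array left out the numbers of called lists ranged from 13 to 14, 8 to 9, 6 to 8 (difference) and 9 to 10.

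Signal over background limits the low genes. Values under the floor of 8.08 were raised to it, so changes of genes near it, such as CHAC1, DMP1, DHFRP3 and TCP10L3, are bounded by the floor.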

Other observations

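Gene families outside the fixed lists were examined after the data were seen. At 3 h the probe-set signals of replication-dependent histone genes were lower, 0 of 39 higher and 14 lower (mean -0.57, camera adjusted p = 1.5e-06, adjusted p = 0.041 with an estimated correlation), for example H2AC6 (-1.45), H2AC25 (-1.29) and H1-2 (-0.82). At 24 h their mean was -0.18, with 1 higher and 10 lower (adjusted p = 0.11). Splicing factors and hnRNPs were higher at 3 h, 12 of 47 with 1 lower (mean 0.16, adjusted p = 0.0016, adjusted p = 0.041 with an estimated correlation). Mitochondrial import genes were higher in 10 of 16 and lower in 1 (mean 0.49, adjusted p = 8.2e-05, adjusted p = 0.062 with an estimated correlation), led by TIMM8A (1.44) and TOMM40 (1.35). Mitochondrial ribosomal proteins were higher in 12 of 48 with 0 lower (mean 0.21, adjusted p = 0.00058, adjusted p = 0.079 with an estimated correlation), chaperonin subunits in 4 of 9 with 0 lower (mean 0.29, adjusted p = 0.0016, adjusted p = 0.053 with an estimated correlation), and subunits of RNA polymerase I and III in 7 of 13 with 1 lower (mean 0.39, adjusted p = 0.0079, adjusted p = 0.062 with an estimated correlation). At 24 h mitochondrial ribosomal proteins were higher in 12 and lower in 1 (mean 0.19, adjusted p = 0.0017, adjusted p = 0.18 with an estimated correlation), with no called difference between the times (adjusted p = 0.95). Mitochondrial import genes were then higher in 7 and lower in 1 (mean 0.25, adjusted p = 0.0057, adjusted p = 0.22 with an estimated correlation), while chaperonin subunits and RNA polymerase I and III (adjusted p = 0.71 each) and splicing factors and hnRNPs (adjusted p = 0.37) were not called. The camera test called a higher effect at 24 h than at 3 h for kinesins (adjusted p = 8.9e-05), some of them in the mitosis list, and histones (0.011). A lower one was called for mitochondrial import and chaperonin subunits (0.026 each), and for RNA polymerase I and III and DEAD-box helicases (0.034 each). None of these differences held with an estimated correlation (adjusted p from 0.18 to 0.34).

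Metallothionein genes were lower at both times, in 5 of 8 at 3 h (mean -0.52, adjusted p = 0.0016, adjusted p = 0.21 with an estimated correlation) and in 7 of 8 at 24 h (mean -0.72, adjusted p = 0.00090, adjusted p = 0.27 with an estimated correlation). At 24 h proteasome subunits were higher in 15 of 33 and lower in 2 (mean 0.17, adjusted p = 0.0017, adjusted p = 0.18 with an estimated correlation), tubulins higher in 8 of 17 with 0 lower (mean 0.33, adjusted p = 0.0017, adjusted p = 0.066 with an estimated correlation) and nuclear transport receptors in 7 of 18 with 0 lower (mean 0.31, adjusted p = 0.0017, adjusted p = 0.066 with an estimated correlation). At 3 h tubulins were higher in 5 and lower in 1 (mean 0.32, adjusted p = 0.0039, adjusted p = 0.053 with an estimated correlation), and the difference between the times was not called (mean 0.014, adjusted p = 0.97). Nuclear transport receptors at 3 h were higher in 5 with 0 lower (adjusted p = 0.040, adjusted p = 0.099 with an estimated correlation) and proteasome subunits higher in 5 and lower in 1 (adjusted p = 0.040, adjusted p = 0.20 with an estimated correlation), and neither difference was called (adjusted p = 0.32 and 0.11). These directions at 3 h and at 24 h were the same under the deposited and the median scaling. Of 57 cytosolic ribosomal proteins 1 was higher and 1 lower at 3 h, and their direction flipped with the scaling, so none is given. Histone and metallothionein members are close in sequence, and cross-hybridization between them was not checked. Whether the histone signals follow total histone mRNA was not tested.

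Tests of the axis below and of a weak array were chosen after the results were seen, and the test of a mislabelled array beforehand. Within groups, replicates spread along 1 axis holding 25.7 percent of the within-group variance. Its absolute correlation with the 3'/5' ratio over 11 arrays was 0.79 (exact permutation p within groups 0.012, 0.023 adjusted for both measures), a candidate source of this spread. For the hybridization signal the absolute correlation was also 0.79 (exact permutation p = 0.10), so that measure cannot be told apart from chance with 11 arrays. No biological explanation was tested for this axis.

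Control replicate 2 of 24 h carried almost no poly-A spike-in signal, 6.19 against 78.8 to 213.8 on the other arrays. Its profile correlated better with its own group's other arrays than with another group, by 0.24 (0.41 against 0.17), which argues against a mislabelled array. The share of probe sets at the lowest deposited value was 3.59 percent, inside the range of 3.49 to 4.21. Its hybridization signal was 1273 within 649 to 1327, so the array was not the weakest by either measure. The deposited array medians lay close together, between 59.2 and 64.1, and neither measure follows the labelling of the sample. A failed labelling or a weak sample therefore stays open. Spike-ins left out of that preparation are a further explanation that was not tested. Control replicate 1 of 24 h had the lowest hybridization signal, 649, and the array weight 0.42.

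Arrays of the same group correlated from 0.977 to 0.987 (median 0.982) and arrays of different groups from 0.965 to 0.981 (median 0.973). The leading principal component held 30.3 percent of the variance and the next 14.4 percent. Genes called at either time numbered 3776, of which 836 were also called for the difference.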
